A study of Mus musculus with 12 samples.

How the data were processed

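The samples were cardiac progenitor cells differentiated from mouse embryonic stem cells and harvested on day 6, with or without 500 ng/ml doxycycline for 24 hours from day 5. Each of the 6 groups (GLI1 pulldown, H3K27ac immunoprecipitation and input, each from dox and from control cells) held 2 samples. Tagged GLI1 was captured on streptavidin beads, and H3K27ac with an antibody. Per the submitters' processing notes, Bowtie2 2.3.2, SAMtools 1.5 and MACS2 2.1.1 were used with the mouse build mm10; the role of each tool is not given there.

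The authors pooled the replicates of a group and called peaks on the pool, so each list stands for 2 samples and holds no spread between them. In both H3K27ac lists the deposited value per summit is a fold enrichment, a ratio of the pileup to the local background of the same pool, and its significance is the deposited −log10 p and −log10 q of the authors' peak caller. The lowest −log10 q was 1.31 in the control list and 1.33 in the dox list, just above the value of a q threshold of 0.05. The GLI1 list holds the authors' windows of 101 bp around summits, per the deposited name found in both replicates and holding a Gli motif, with a −log10 q for each. How replication and the motif were judged is not stated, and no genome sequence was at hand to search the motif again. Lists of the control GLI1 pulldown and of the inputs were not analysed here, so no GLI1 signal of uninduced cells stands beside the GLI1 sites.

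The number of reads per library is unknown from the lists. Whole-number pileups and backgrounds that return the deposited fold enrichment and −log10 p within 0.01 were found for 99.96% of the control summits and 99.92% of the dox summits. The uniform background recovered this way was 2.83 reads in the control list and 3.63 in the dox list, a ratio of 1.28, which was taken as the ratio of depths. Counting intervals for single regions were computed from these pileups and cover counting error only. Running peak numbers skip in 694 stretches (937 numbers in the control list and 999 in the dox list), which were read as peaks the authors had removed. The 1511 protein-coding genes with an end in such a stretch were not analysed, and a region of 1 list that lay in a skipped stretch of the other was not named; the latter was decided after such a region had been seen among the strongest.

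Summits of 1 interval were collapsed, and intervals of both lists that shared at least 1 bp were merged into 94481 regions, called shared, dox-only or control-only. For a shared region, the highest fold enrichment in dox was divided by the highest in control, and the log2 ratio was centred on the median of all shared regions. The ratio is one of fold enrichments of separately called lists without a common scale, so it places a region relative to the other shared regions. Regions with a centred log2 ratio of at least 1 in size are described as higher or lower. GLI1 sites were counted as lying in a peak when they shared at least 1 bp with it, and the count was repeated after moving all sites by 10000 and 100000 bp in both directions.

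Genes came from a GRCm38.p6 table of 21887 protein-coding genes that gives the outer coordinates of a gene but neither strand nor exons. Windows around transcription start sites, set out at first, were therefore replaced by windows of 1000 bp around both annotated ends, called gene ends here, and a division into exons and introns was not run. A gene took the highest fold enrichment among the regions at its ends in each list, so its control and dox values can come from different regions. The first version of this measure used the intervals of each list separately. It was replaced after its values had been seen, because an interval edge crossing the window border in 1 list alone changed a gene's ratio; for the sarcomere list the median was −0.74 by intervals and −0.18 by regions. The first version is kept among the alternatives.

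Gene lists (hedgehog pathway and direct GLI targets, sarcomere and calcium handling, cardiac transcription factors, mesoderm and second heart field progenitor, endothelial and blood, smooth muscle and mesenchyme, neural, pluripotency, endoderm, housekeeping), the main comparisons, the rule for named genes and a first set of alternatives were set before the data were examined. Not in that plan were the groups of sites by strength and the split of the hedgehog list by GLI1 sites. Nor were the balance of dox-only and control-only regions near list genes, or the comparison of all genes by GLI1 site. A list's median was placed among 10000 random lists of equal size matched on deciles of mean fold enrichment, and regions with a GLI1 site among 10000 random sets of shared regions matched on deciles of fold enrichment and width. The number of list genes with a GLI1 site within 50000 bp was placed among random lists matched on fold enrichment and gene density. These percentiles describe the lists and are not tests between conditions, since each condition is a single pool. Shares carry exact (Clopper-Pearson) 95% binomial intervals, and medians a 95% interval from order statistics over regions or genes, which are not independent replicates.

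By the rule for named genes, the text names, per list, up to 4 genes with the highest and up to 4 with the lowest ratio and up to 4 with most GLI1 sites within 50000 bp, the 10 strongest regions of each class and direction (for the higher and lower shared regions, with a −log10 q of at least 10 in both lists; for regions with a GLI1 site, without such a minimum), the 5 clusters with most GLI1 sites, and always a set of genes that includes Gli1, Ptch1, Hhip, Foxf1, Nkx2-5, Tnnt2 and Myh6; 1 gene that the rule names is not reported here. Genes with a region in only 1 list, Nkx2-9, Gas1 and Cdon fall outside the rule and were chosen after their values were seen.

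Alternatives covered stricter peaks, equal numbers of peaks, reciprocal overlap, stitching, other scalings, other windows, recovered pileups, and the dox list scaled to the control depth. The depth scaling was tried in 2 versions. The first kept scaled dox summits at the lowest −log10 p of the control list. The second held both lists to a −log10 p of 6.88, and was chosen after the value of the first had been seen, because a peak caller also asks for a length that the scaled summits were not held to. The same −log10 p was then also applied without scaling, to hold the threshold apart from the depth. The procedure was tested on simulated data: of 3000 simulated regions 100% were put in the right class, 97.9% of 2960 pileups were recovered, and 15 genes shifted by −0.5 fell below the lowest 2.5% of random lists in 79.5% of 200 repeats, against 5.0% outside both limits for unshifted genes. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used.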

Results

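H3K27ac, a histone mark of active promoters and enhancers, and binding sites of tagged GLI1, a transcription factor of the Hedgehog pathway, were profiled by chromatin immunoprecipitation and sequencing in mouse cardiac progenitor cells (line GLI1-FTA, made in A2Lox.cre embryonic stem cells). Doxycycline was given for 24 hours to express GLI1, and untreated cells of day 6 were the control. The 12 samples formed 6 groups of 2. Values came from 3 lists that each pooled the replicates of a group: 2605 GLI1 sites from dox cells, 67463 H3K27ac intervals (59.9 Mb) from control cells and 76437 (66.0 Mb) from dox cells. With a single pooled list per condition there were no replicates to compare, so differences between conditions were not tested and no p-value is given. Fold enrichments are the authors' values. Ratios are log2 ratios of dox over control fold enrichment, centred on the median of all shared regions, which was −0.13 before centring.

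The first comparison asked what H3K27ac looked like at Hedgehog pathway genes when GLI1 was induced. Fold enrichment at the ends of Hhip, whose product binds and sequesters Hedgehog ligands (chromosome 8, 79965850 to 80058060), was 5.15 in control and 21.6 in dox cells, a log2 ratio of 2.20, and Gli1 itself (chromosome 10, 127329882 to 127341579) had 9.03 and 35.4. Ptch1, the main Hedgehog receptor (chromosome 13, 63508328 to 63573460), was already at 25.0 in control cells and stood at 50.7 in dox cells, a log2 ratio of 1.15. The forkhead factor gene Foxf1 (chromosome 8, 121084386 to 121088154) had a region at its ends in dox cells alone, with a fold enrichment of 40.2.

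Of the 40 analysed genes of the hedgehog list, 29 had a region at a gene end in both lists, 5 in dox alone, none in control alone and 6 in neither. Genes with a log2 ratio of at least 1 included Foxl1 (2.64), Foxc2 (2.42), Hhip, Gli1, Nkx2-9 (1.74) and Ptch1. For Foxl1 the 2 values came from different regions. The control value of 4.86 lay in a region with 16.5 in dox cells, and the dox value of 27.7 in a neighbouring dox-only region. The 5 with a region in dox alone were Foxf1, Foxf2 (fold enrichment 21.4), Tbx1 (3.74), Osr1 (3.67) and Foxd1 (2.59). The lowest values were those of Gli3 (−0.89) and Gli2 (−0.54), the other GLI factors, of the cell cycle kinase gene Cdk6 (−0.52), and of Boc (−0.76), which encodes a Hedgehog co-receptor. The co-receptor genes Gas1 and Cdon stood at −0.38 and −0.32. Without centring Gli3 had −1.02, and with the strongest region in the whole gene Boc had −1.20 and Evc2 −1.14. The list's median of 0.20 (95% interval −0.28 to 0.66) lay at the 66.4th percentile of matched random lists. The 14 measured genes with a GLI1 site within 50000 bp had a median of 0.99 (0.20 to 2.42), and the 15 without had −0.18 (−0.40 to 0.00). When regions up to 5000 bp from a gene end were taken, the list lay at the 3.06th percentile.

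GLI1 sites were dense around Hedgehog pathway genes. Of the list's genes, 19 had a site within 50000 bp, against a median of 6 in random lists matched on H3K27ac and gene density, and no random list had as many. Ptch1 had 10 sites in this window, Snai1 and Sufu 6 each, and Gli1 4. Sufu, which encodes a cytoplasmic inhibitor of GLI factors, had a log2 ratio of 0.50, and so had Snai1. Added over the list's genes, 223 dox-only and 115 control-only regions lay within 50000 bp. A region near more than 1 list gene, as around Foxf1, Foxc2 and Foxl1, was counted for each. The difference of 108 stood against a median of 27 in random lists (99.8th percentile), which did not keep neighbouring genes together.

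The largest groups of sites lay at a few loci. A cluster of 18 sites on chromosome 13 (63476156 to 63731937) spanned Ptch1 and Fancc, with all 18 sites in regions of the dox list, and the median log2 ratio of its 7 shared regions was 3.03. On chromosome 8 (120825519 to 121127627), 17 sites ran through Foxf1, Mthfsd and Foxc2, where 9 of the 16 regions that held a site were dox-only and the 7 shared ones had a median of 1.89. A cluster of 12 sites lay at Ercc6l2 (chromosome 13, 63899009 to 64035284; median 2.16) and one of 9 at Pkdcc (chromosome 17, 83075003 to 83238560; median 0.86). A cluster of 8 on chromosome 13 (28554962 to 28811781; median 1.82) held no protein-coding gene, and the nearest, Sox4, was 137138 bp away.

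**Figure D1:**
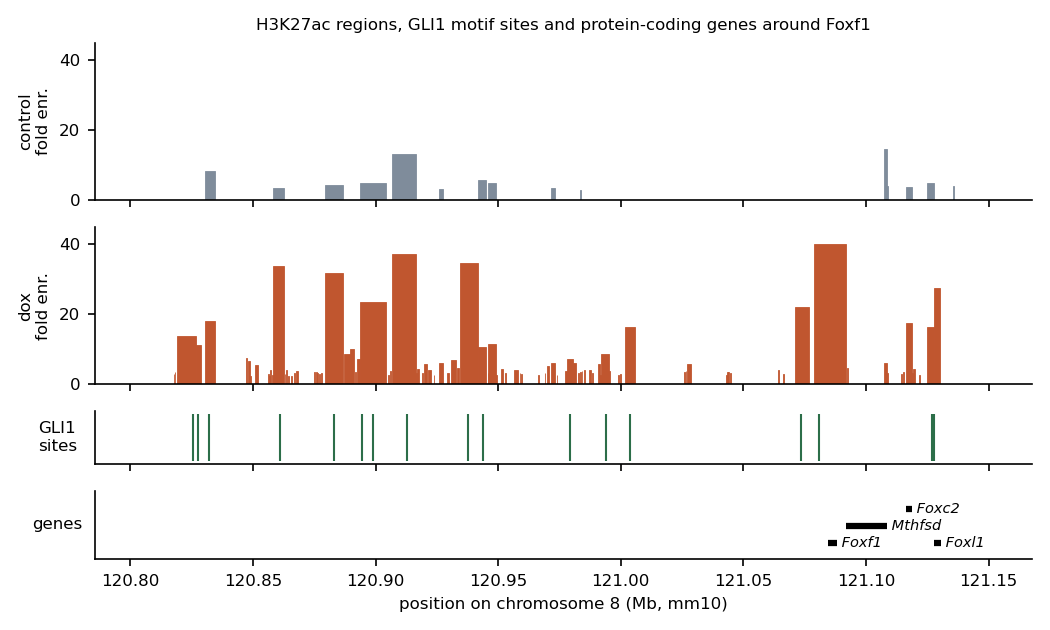
Map of the Foxf1 locus on chromosome 8 (position in Mb, mm10). Bars are H3K27ac regions, with the highest fold enrichment of the control list (upper row) and of the dox list (second row) as height; green lines are GLI1 sites and black bars protein-coding genes. The region at Foxf1 reached 40.2 in dox cells and had no control peak.

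The next comparison asked whether GLI1 sites lay in acetylated chromatin in untreated and in induced cells. Of the 2605 sites, 651 (25.0%, 95% interval 23.3 to 26.7) lay in a control H3K27ac peak and 1955 (75.0%, 73.3 to 76.7) in a dox peak. In dox peaks alone lay 1317 sites (50.6%), in control peaks alone 13 (0.50%), and in neither 637 (24.5%). After all sites had been moved by 10000 or 100000 bp, between 3.72% and 7.49% lay in control peaks and between 5.49% and 12.8% in dox peaks. Only 127 sites (4.88%) were within 1000 bp of a gene end, 1159 (44.5%) were farther inside a gene and 1319 (50.6%) lay between genes. Another site lay within 100000 bp of 48.0% of the sites. When the sites were widened by 500 bp on each side, the share in neither list was 8.18%.

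**Figure D2:**
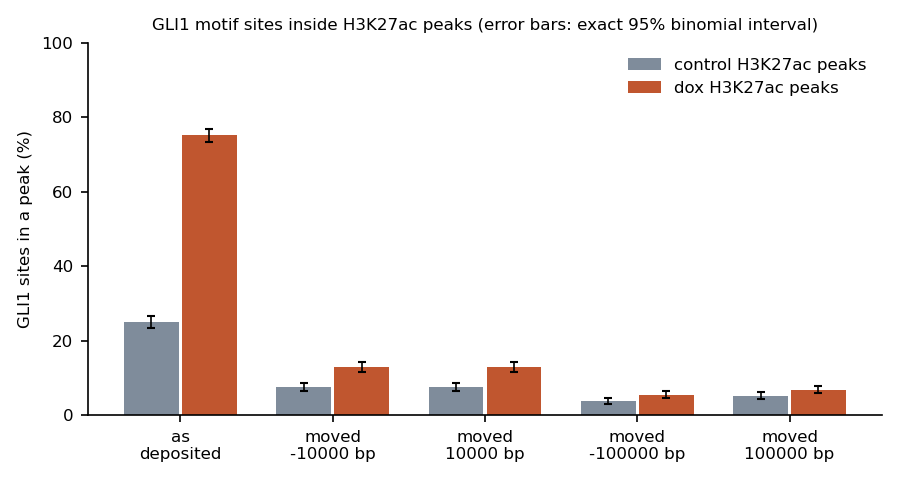
Share of the 2605 GLI1 sites (percent, vertical axis) inside control and dox H3K27ac peaks, as deposited and after all sites were moved by the distance shown. Error bars are exact 95% binomial intervals; as deposited, 25.0% lay in control and 75.0% in dox peaks.

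Shared regions with a GLI1 site had higher ratios than other shared regions. The steepest was a region of 4574 bp on chromosome 14 (75880100 to 75884673) 12255 bp from Gtf2f2, with a fold enrichment of 3.13 in control and 42.3 in dox cells, a log2 ratio of 3.89. A region at Sox18, an endothelial transcription factor gene (chromosome 2, 181669897 to 181678134), had 3.56 and 33.1, a log2 ratio of 3.35, and held 2 sites. The control peaks of these regions were weak, with a −log10 q of 2.63 and 5.35. The 783 shared regions with a site had a median log2 ratio of 1.03 (95% interval 0.90 to 1.15), or 2.04-fold, and 85.8% of them were above 0. Random shared regions without a site, matched on fold enrichment and width, had a median of −0.18, and the highest of 10000 random sets had −0.042; matched on control fold enrichment instead, random sets had a median of 0.29. The 630 regions away from gene ends had a median of 1.17 (1.07 to 1.29) and the 153 at gene ends 0.52 (0.39 to 0.69). With only peaks of a −log10 q of at least 10 the median was 0.54, and with width-weighted mean fold enrichments it was 0.74 and the region at Sox18 had 1.71.

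**Figure D3:**
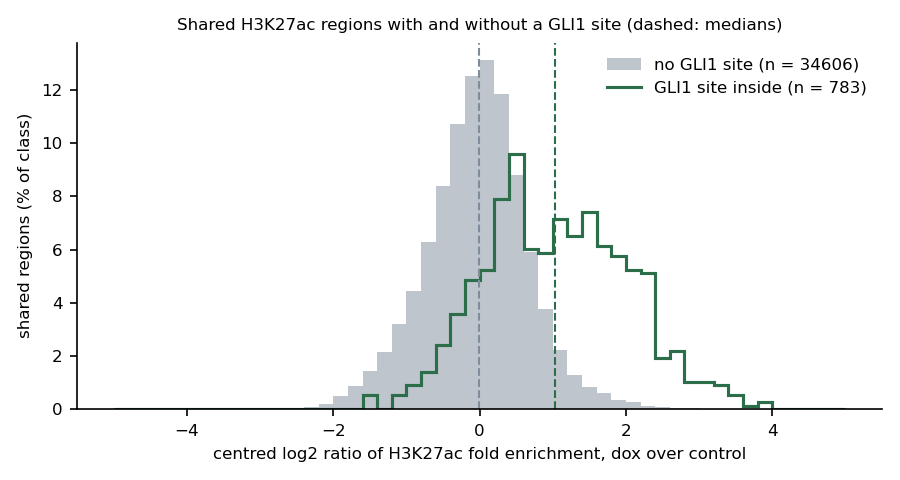
Distribution of the centred log2 ratio of H3K27ac fold enrichment, dox over control (horizontal axis), for shared regions with a GLI1 site (green line) and without (grey), as percent of each class. Dashed lines are the medians, 1.03 with a site and −0.01 without.

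Stronger sites lay in regions with higher ratios. Over 4 groups of sites, from the weakest to the strongest by the authors' −log10 q, the median log2 ratio at sites in shared regions was 0.71 (0.47 to 0.91), 0.83 (0.60 to 1.01), 1.16 (0.92 to 1.40) and 1.51 (1.26 to 1.66). The share of sites in a region present in the dox list was 68.2% in the weakest and 87.6% in the strongest group, while the share in a region present in the control list was 36.4% and 36.6%. Across 921 sites Spearman's rho between −log10 q and the log2 ratio was 0.28. Sites are not independent replicates. For sites in a region of the dox list, the median dox fold enrichment was 10.7, 10.6, 13.2 and 20.3 over the 4 groups. Dox fold enrichment is part of the ratio, and a trend apart from it was not tested. By number of sites, the median ratio was 1.01 in 664 shared regions with 1 site, 1.20 in 103 with 2 and 0.63 in 16 with 3 or more. Each site took the ratio of its whole merged region. While 921 sites lay in shared regions, only 638 lay in both a control and a dox peak. For the others a value can come from a peak elsewhere in the region.

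**Figure D4:**
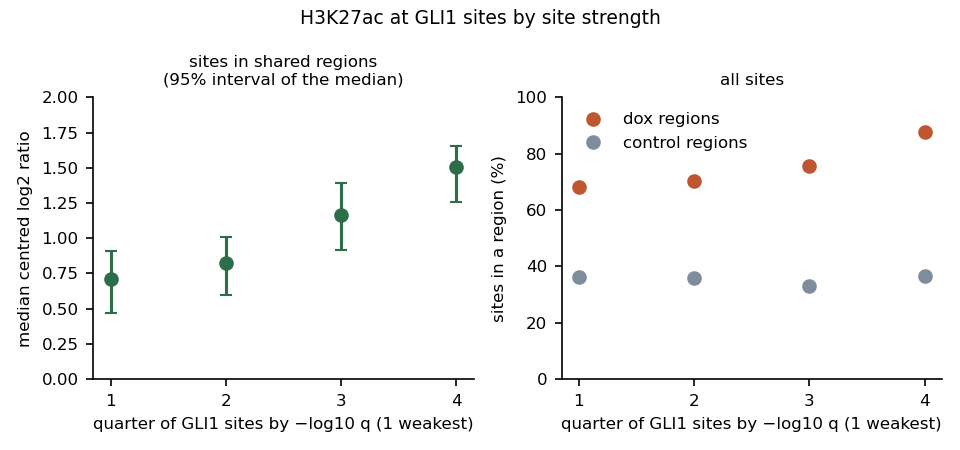
GLI1 sites in 4 groups by −log10 q (horizontal axis, 1 the weakest). Left, median over sites of the centred log2 ratio of H3K27ac of the shared merged region that held the site, with its 95% interval, from 0.71 to 1.51. Right, percent of all sites in a merged region present in the dox list (68.2% to 87.6%) or in the control list.

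Genes of the contractile apparatus had lower ratios than matched genes. At Tnnt2, the gene of cardiac troponin T (chromosome 1, 135836315 to 135852268), fold enrichment was 10.4 in control and 3.74 in dox cells, a log2 ratio of −1.35. Csrp3, a muscle LIM protein gene (chromosome 7, 48830398 to 48848051), had 11.0 and 3.02 (−1.73), Slc8a1, the sodium-calcium exchanger gene, had −1.14 and Ankrd1, a gene of a cardiac ankyrin repeat protein, −1.06. Regions at gene ends of Actc1, Myl7, Ttn, Ldb3, Smpx, Ryr2 and Nppb were in the control list alone, with fold enrichments of 3.35 (Myl7) to 7.83 (Ttn), and those of Myl3 (8.66) and Myl4 (2.82) in the dox list alone. Casq2, which encodes the calcium store protein of the sarcoplasmic reticulum, had 7.48 in control and 15.6 in dox cells (1.19). Gja5 (0.50), Tpm1 (0.36) and Gja1 (0.26) were also above 0, and Myh6 had no region at a gene end in either list.

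Of the 40 genes of this sarcomere and calcium handling list, 16 had a region in both lists, 2 in dox alone, 7 in control alone and 15 in neither. The median log2 ratio of −0.18 (95% interval −1.06 to 0.26) lay at the 0.72nd percentile of matched random lists, whose median was 0.14. Added over the list's genes, 137 dox-only and 175 control-only regions lay within 50000 bp, a balance at the 0.405th percentile of random lists. A region near more than 1 list gene, as around Myh6 and Myh7 or Nppa and Nppb, was counted for each, and the random lists did not keep neighbouring genes together. A GLI1 site lay within 50000 bp of 9 of the genes, against a median of 5 in random lists (94.6th percentile); Casq2, Myl3, Tpm1 and Xirp1 (−0.098) had 2 sites each, and Csrp3 and Slc8a1 were among those with 1. By the intervals of each list separately, the median was −0.74, Slc8a1 had −1.74 and Gja5 1.31, and with the strongest region in the whole gene Csrp3 had −0.42.

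Cardiac transcription factor genes also had lower ratios than matched genes. Myocd, which encodes a coactivator of muscle genes (chromosome 11, 65173608 to 65269989), had a fold enrichment of 14.3 in control and 4.32 in dox cells (log2 ratio −1.60), and Hand2, a factor of heart field development (chromosome 8, 57320983 to 57324517), 24.5 and 10.8 (−1.05). Tbx3 had −1.17 and Gata5 −1.14. Nr2f2, an atrial and venous regulator, was highest at 0.97, followed by Nr2f1 and Srf (0.38 each) and Meis1 (0.28). Of the 30 genes, 19 had a region in both lists, 2 (Hopx and Tbx18) in dox alone and 9, Nkx2-5 among them, in neither. The median was −0.32 (−0.59 to 0.19), at the 0.01st percentile of random lists. Added over these genes, 83 dox-only and 141 control-only regions lay within 50000 bp, a balance also at the 0.01st percentile. A GLI1 site lay within 50000 bp of 8 of the genes (random median 4), with Hand2 1307 bp and Nkx2-5 7149 bp from the nearest. With the strongest region in the whole gene Myocd had −0.86.

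**Figure D5:**
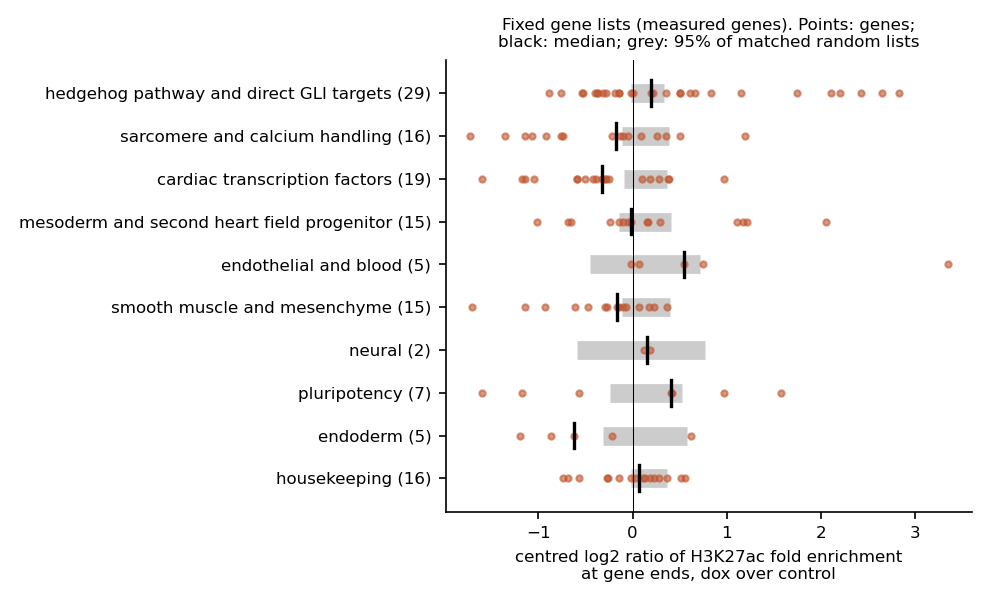
Centred log2 ratio of H3K27ac fold enrichment at gene ends (horizontal axis) for the fixed gene lists, with the number of measured genes in brackets. Points are genes, black bars list medians, and grey bars the middle 95% of matched random lists. The medians of the sarcomere (−0.18), cardiac transcription factor (−0.32), smooth muscle and mesenchyme (−0.16) and endoderm (−0.62) lists lie below the grey bars.

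Progenitor genes of mesoderm and the second heart field showed no common direction. Tbx6, a factor of paraxial mesoderm, had 5.12 in control and 19.4 in dox cells (log2 ratio 2.05), and Six2 (1.21), Tcf21 (1.17) and Pdgfra (1.11) were also higher, whereas Wnt2b (−1.01), Mesp2 (−0.68), Fgf10 (−0.65) and Foxp1 (−0.24) were lowest. The 15 measured genes of 34 had a median of −0.02, at the 12.9th percentile. Taking regions up to 5000 bp from a gene end, Tbx6 had 0.39, Pdgfra 0.20 and Wnt2b −0.40.

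Lists for other cell types were measured at fewer genes. In the smooth muscle and mesenchyme list, Col1a1 (−1.70), Snai2 (−1.14), Tagln (−0.93) and Lmod1 (−0.61) were lowest and Col3a1 (0.36) highest, and the median of the 15 measured genes, −0.16, lay at the 1.11th percentile, or the 5.38th with the strongest region in the whole gene, and Col1a1 had −0.30 within 5000 bp of a gene end. In the endothelial and blood list 5 genes were measured, with a median of 0.54 (93.1st percentile) and Sox18 at the top; up to 5000 bp from a gene end 13 genes had a median of 0.05. In the endoderm list, Apoa2 had −1.19, Krt19 −0.86, Krt8 −0.62 and Foxa3 0.62, and the median of 5 genes, −0.62, lay at the 0.17th percentile; with all shared regions within 50000 bp it lay at the 81.9th, and Apoa2 had −0.63 within 5000 bp of a gene end. Of the endoderm genes, 3 had a region at a gene end in dox alone and 1 in control alone. Added over the endoderm genes, 75 dox-only and 27 control-only regions lay within 50000 bp, a balance at the 99.4th percentile. Foxa2, a factor of the floor plate and endoderm that stands in both the neural and the endoderm list, had a region in dox alone with a fold enrichment of 34.0 and 2 GLI1 sites within 50000 bp. The other measured neural genes, Sox2 and Nes, had a median of 0.16 (51.6th percentile, or the 98.0th by the intervals of each list separately). In the pluripotency list Tet2 (1.58) and Sall4 (0.97) were highest and Tdgf1 (−1.60) lowest, with a median of 0.41 at the 92.3rd percentile, but at the lowest end of random lists (below all of them, median −0.57) with all shared regions within 50000 bp. Housekeeping genes had a median of 0.07 (14.8th percentile), which is below 0 without centring.

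Over the whole genome, the peak lists overlapped in part. The strongest dox-only regions lay 47321 bp from Ercc6l2 (fold enrichment 40.3), at Foxf1 (40.2) and 11093 bp from Prdm8 (40.0), and 9 of the 10 strongest held a GLI1 site. The strongest control-only regions lay at Ccl17 (21.7) and near Msx2 (21.4), a homeobox gene, and 0 of the 10 strongest held a site. Of 94481 regions, 35389 (37.5%) were shared, 33496 (35.5%) were dox-only and 25596 (27.1%) control-only. A GLI1 site lay in 974 dox-only (2.91%), 783 shared (2.21%) and 3 control-only regions (0.012%). The odds ratio was 255 for dox-only against control-only regions, which rests on those 3, and 1.32 for dox-only against shared regions. The sites were called in dox cells alone. There were 1.31 dox-only regions per control-only region. With both lists held to a −log10 p of 6.88 the ratio was 1.26, and 0.80 (13044 and 16227 regions) when the dox list was also scaled to the control depth; scaled at the lowest control −log10 p instead, it was 1.24. With a −log10 q of at least 10 there were 9165 dox-only and 8216 control-only regions.

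Shared regions with the highest and the lowest ratios differed in GLI1 sites. In a region 68661 bp from Hsd17b3 (chromosome 13, 63973941 to 63989613) fold enrichment was 7.31 in control and 54.4 in dox cells (log2 ratio 3.03), and in one 195801 bp from Fgfr2, a fibroblast growth factor receptor gene, it was 4.93 and 33.5 (2.90). At Tuba1b, an alpha tubulin gene (chromosome 15, 98934597 to 98936258), it was 31.0 and 4.58 (−2.63; −1.40 by the recovered pileups of 121 and 49 reads, without their backgrounds), and 57218 bp from Popdc3, a gene of a muscle membrane protein, 31.9 and 5.62 (−2.38). With width-weighted means the first 2 of these regions had 2.05 and 1.75. Of the 10 strongest higher regions 8 held a GLI1 site, and of the 10 strongest lower regions 0. Across all shared regions, 2399 (6.78%) were higher and 2940 (8.31%) lower, and a site lay in 401 (16.7%) of the higher, 8 (0.27%) of the lower and 1.24% of the others. Higher regions made up 44.9% of those past the limit, and 31.7% without centring. At protein-coding genes, 368 of the 9761 measured genes were higher and 200 lower: 8.40% of the genes with a GLI1 site within 50000 bp were higher, against 2.91% of the others, while 2.15% and 2.03% were lower. The medians of the 2 groups were close, 0.18 for the 1535 genes with such a site and 0.13 for the 8226 without.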

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

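Alternatives with scaled depth, a common −log10 p, skipped stretches, recovered pileups, a fold enrichment minimum, separate intervals, the strongest region in the gene or without genes near a GLI1 site were chosen after the results were seen. No paired analysis was possible because the labels share replicate numbers but the lists are pooled, and leave-one-out could not be run for the same reason. Library depths are unknown, and a region of 1 list alone can lie just under the threshold of the other. Under alternatives, 120 of 173 values of the main results stayed within the limits set for them. Of 365 values of named genes, 347 lay within 0.5 of the main log2 ratio, a limit chosen by convention, while 6 had the other sign and 18 lay on the other side of 1 in size. Of 150 values of named shared regions, 127 lay within the counting interval and none had the other sign; 19 of the 30 named shared regions moved beyond their counting interval with width-weighted means. Stricter or different rules for peaks changed counts by their construction. With a −log10 q of at least 5 there were 18071 dox-only and 14256 control-only regions. With at least 10 there were 17627 shared, 9165 dox-only and 8216 control-only regions, with equal numbers of the strongest peaks 20586, 11475 and 11166, and with 50% reciprocal overlap 23534, 52903 and 43929. Stitching within 1000 bp gave 16604 dox-only and 11137 control-only regions, and a −log10 q of at least 10 for condition-only regions gave 5528 and 2898. With the dox list scaled to the control depth at a common −log10 p there were 23399 shared, 13044 dox-only and 16227 control-only regions, so the ratio reversed to 0.80, while that −log10 p without scaling gave 17987 dox-only and 14282 control-only regions, a ratio of 1.26; the first version of the scaling, at the lowest control −log10 p, gave 1.24. Which of the 2 is nearer to equal depth was not tested. The share of higher regions among those past the limit was 31.7% without centring, 48.1% with quantile normalization, 49.2% with width-weighted means (1748 lower), 37.8% with a −log10 q of at least 10 (688 higher, 1130 lower), 46.3% with recovered pileups and 38.9% with a fold enrichment of at least 5 (734 higher, 1154 lower). Widened sites lay in control peaks for 32.8%, in dox peaks for 91.6%, in dox alone for 59.0% and in neither for 8.18%. With a −log10 q of at least 10 the shares were 19.7% in control, 69.8% in dox and 29.8% in neither, and with scaled depth 22.8%, 72.4% and 27.1%. The median log2 ratio of regions with a GLI1 site was 0.74 with width-weighted means, 0.87 with sites within 1000 bp, 1.17 away from gene ends, 0.54 with a −log10 q of at least 10 and 0.55 with a fold enrichment of at least 5. It stayed above every matched random set in these alternatives. The odds ratio of holding a site, dox-only against control-only regions, was 91.2 with sites within 1000 bp. Percentiles of gene lists were 0.26 for the hedgehog list without genes near a GLI1 site, 5.38 for smooth muscle and mesenchyme with the strongest region in the gene, and 98.0 for the neural list by separate intervals (2 genes). With all shared regions within 50000 bp they were 0.00 for pluripotency and, reversed, 81.9 for endoderm. Beyond the rules for peaks, the cause was not tested.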

Other observations

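The tests on the pulldown, on the scale of the libraries, on doxycycline, on strong peaks in general, on list genes without a GLI1 site nearby, on cell shares and on copies of chromosome X were chosen after the results were seen. Beyond the genes of the fixed lists, several dox-only regions with strong GLI1 sites lay near genes of other functions. A region in Fbxl7 on chromosome 15 had a fold enrichment of 39.3 and 3 GLI1 sites, one near Pigh on chromosome 12 had 39.8 and 2 sites, and one 77587 bp from Tmem100, a gene induced by BMP signalling in endothelium, had 35.9 and 2 sites. Among shared regions with a GLI1 site, one 168777 bp from Dact1, a modulator of Wnt signalling, had a log2 ratio of 3.73 with 30.3 in dox cells, and one in Prex1 had 4.44 and 42.6 (3.39); their control peaks had a −log10 q of 1.56 and 6.10. Lower regions without a site lay in Cbfa2t2 (27.9 and 5.90, log2 ratio −2.11) and 518887 bp from Irx1, a homeobox gene (25.6 and 4.92, −2.25).

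Regions with a GLI1 site had a higher fold enrichment in the dox list (median log2 ratio 1.03). A scale difference of the libraries that keeps the order of regions is removed by quantile normalization, but the median was then still 1.04 (95% interval 0.90 to 1.15), against −0.0076 for regions without a site. A pulldown that recovers any strongly acetylated chromatin would find sites as often in unchanged regions of equal dox fold enrichment, but the odds ratio of holding a site was 12.1 within deciles of dox fold enrichment (44.5% of 384 higher and 4.35% of 2345 unchanged regions in the top decile). This holds for the sites as the authors filtered them. The background of those calls is not stated and no control GLI1 list was analysed, so such a pulldown is not excluded. An effect of doxycycline apart from GLI1 cannot be told apart, since no induced cells without the tagged GLI1 were in the design; 61.3% of the 2399 higher regions lay more than 50000 bp from any site, against 84.3% of lower and 80.8% of all shared regions. A gain of acetylation where GLI1 binds stays open beside it, as a hypothesis found and tested on the same lists.

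The sarcomere and cardiac transcription factor lists had lower ratios than matched random lists. At gene ends the same held for the smooth muscle and mesenchyme list and the endoderm list. Whether low ratios were particular to heart genes stays open. The smooth muscle and mesenchyme list holds 4 contractile genes. The endoderm list was measured at 5 genes and reversed with all shared regions within 50000 bp. The explanations below were examined for the sarcomere and cardiac transcription factor lists. A lower dox fold enrichment at strong peaks in general would show across genes, but Spearman's rho between ratio and fold enrichment was 0.068 across 9761 genes. After quantile normalization rho was −0.079, and the 2 lists lay at the 0.29th and 0.01st percentile of matched random lists. Those percentiles could change little. The random lists were already matched on fold enrichment, and the normalization moved log2 ratios by a median of 0.059. GLI1 sites within 50000 bp of the list genes are not the whole cause. Without the genes that had such a site, the 2 lists still lay at the 1.94th and 0.31st percentile. An effect of sites farther away was not tested. Whether sites lie in the lower regions less often than in others stays open. Of 34 lower regions near these genes 1 held a site (2.94%, 95% interval 0.074 to 15.3), against 3.91% of 281 others. A smaller share of heart muscle cells stays open. It need not raise markers of all other cell types alike, so the lists of those types cannot decide it. The smooth muscle and mesenchyme list lay at the 1.11th percentile. Without its 4 contractile genes it lay at the 2.94th, or the 64.9th with the strongest region in the gene. The endothelial list lay at the 93.1st, or the 38.3rd within 5000 bp of a gene end. For the endoderm list the 2 measures disagreed. Its median over 5 genes lay at the 0.17th percentile, and its balance of dox-only and control-only regions at the 99.4th. A later stage of differentiation in control than in dox cells was not tested.

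Chromosome X had fewer intervals in the dox list (1616) than in the control list (1856), a ratio of 0.871, while the ratio on the 19 autosomes was 1.07 to 1.25. Weaker peaks near the threshold would be lost alike on autosomes, but 58.8% of the control intervals of chromosome X were found again in the dox list, below every matched random set (60.2% to 67.7%), and with a −log10 q of at least 10 the ratio was still 0.899, against 0.980 to 1.11 on autosomes. Fewer copies of chromosome X in dox cells would lower its pileups, but the median log2 ratio of recovered pileups, which are not divided by a background, was −0.093 at 681 shared regions strong in control, at the upper end of matched autosomal sets (−0.23 to −0.093), and 89.4% of strong control intervals were found again against 89.3% on autosomes. No other biological explanation was tested.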
